A study of Mus musculus with 2 samples.

How the data were processed

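The data were H3K4me3 ChIP-seq peak lists from the midbrain of mouse embryos, in 1 group of 2 biological replicates per the labels, which give pools of 120 and 88 embryos aged 12.5 days. The authors deposited 4 peak lists in narrowPeak form on mm10 (GRCm38). Peaks were called on each replicate separately for the replicates' own lists and on both replicates together for the pooled list, per the deposited README. The replicated list was derived from the replicates' lists and the pooled list, per the deposited README, and each of its 23778 lines was identical to a line of the pooled list. The aligner, the peak caller, their versions, the rule for a replicated peak and the threshold are not given in the sources used here. The smallest −log10 p was 2.02 in replicate 1's deposited list, 2.00 in replicate 2's, 2.01 in the pooled list and 2.05 in the replicated list. The −log10 q was below 2 in 11.1%, 10.4%, 9.44% and 0.400% of the peaks of these deposited lists, so most of the weakest peaks are absent from the replicated list. The deposited signal value of a peak (column 7) and its −log10 p and −log10 q are the authors' own; what the signal is relative to is not given in the sources used here, and it was used only to rank peaks within a list. The lists hold no read counts, so the depth of each library is unknown and no interval that needs it is given. A deeper library can list more weak peaks, and depth could therefore change the number of peaks and the width of domains.

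Coordinates were compared with the GENCODE M21 annotation and the RefSeq sequence and annotation of GRCm38, whose chromosome names and lengths fit mm10. Peaks on unplaced scaffolds (17, 16, 24 and 13 in the replicate 1, replicate 2, pooled and replicated lists) were left out wherever genes were involved. Intervals were compared with bedtools 2.31.1 and with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1); sequence was read with samtools 1.23.1 and pysam 0.24.0, and plots were drawn with matplotlib 3.10.9. Peaks of different lists were shared if they overlapped by at least 1 bp. A gene was marked if a replicated peak lay within 1 kb of any TSS of its transcripts in the GENCODE basic set, for 21938 protein-coding genes on chromosomes 1 to 19, X and Y. Peaks within 1 kb of each other were joined into a domain, and the width of a gene's widest promoter domain was its domain width. Distal peaks were those more than 5 kb from every annotated TSS of any gene type in the comprehensive set. Promoter CpG content was the observed/expected ratio within 500 bp of the TSS, taken at the TSS with the highest value and divided into deciles.

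The 34 gene lists, of which 26 were lists of symbols and 8 families defined by name, were written before the data were examined, as were the tests, the thresholds, the other settings listed below and the rule for named genes. The lists cover midbrain lineages, neighbouring brain regions, neural cell classes, markers of other cell types that dissected tissue may hold, and gene families. Among 366 genes in the symbol lists, 6 were in more than 1 symbol list (Gata1, Hoxa2, Hoxb1, Lmx1b, Sox10 and Sox17). Overlap with the 8 families was not counted. Zic1, Krt10 and Krt8, for example, were each in a symbol list and in a family. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 34 lists. The share marked was also compared with 10000 random lists of the same size matched on CpG decile, a permutation of list membership within deciles. Median domain width was compared with 10000 random lists of marked genes matched in the same way, two-sided, adjusted over the 27 lists with at least 5 marked genes. The smallest random-list p is 0.0002 before adjustment. The share of peaks near a TSS and the overlap of the replicates were compared with 100 shuffles of peak positions within chromosomes, gaps in the assembly included. Genes are not replicates, so these tests describe these libraries. An adjusted p below 0.05 was called. Values with an SD come from the replicates' own lists.

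The rule for named genes took, of each list called by Fisher's test or by width, the 3 marked genes with the widest domains and the unmarked genes, or the first 5 of these in list order where there were more. Of each other symbol list it took the 2 widest, and over all genes the 20 widest. It also took the 5 replicated peaks of highest signal, the 5 widest distal domains and, per replicate, the 5 peaks of highest signal absent from the other list. Gypa, Th, Ddc, Aldh1a1, Col1a1, Col1a2, Pdgfrb, the promoter domain of En2 and the genes of the closing observations were named after their values were seen.

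The functions were tested on simulated data. Interval overlaps differed from a brute-force count in 0 of 4000 cases. With 21938 simulated genes, 0 of 100 null lists were called for the share marked and 0 of 100 for width. Of the planted lists, 20 of 20 with a raised share and 19 of 20 with 2-fold wider domains were recovered. The lists with a raised share were drawn from the lower CpG deciles only and were marked nearly throughout. Their recovery does not show that a higher share could be found where matched genes are nearly all marked. The simulated widths did not depend on CpG decile and no domains were shared. The null lists therefore do not check the CpG matching of widths or the effect of shared domains. The alternatives were a −log10 q of at least 10, each replicate's own list or the pooled list in place of the replicated list, promoter windows of 500 bp and 2.5 kb, the most upstream TSS only, no joining or joining within 3 kb, distal limits of 2.5 and 10 kb, CpG content within 250 bp, genes of the upper 5 CpG deciles only (for shares), and stricter definitions of overlap. Further alternatives, chosen after seeing the data, left out genes that share a domain, took widths in the upper 5 CpG deciles, used the comprehensive TSS set and added RefSeq start sites to the distal limit. For the closing observations, distal peaks were compared with RefSeq transcript and tRNA starts within 1 kb and with shuffled positions that also lay more than 5 kb from every GENCODE TSS, with 100 shuffles for start sites and 5 for CpG content, which was taken over the whole peak. Domain widths of the neural lists were also compared with lists matched on CpG decile together with the number of annotated start sites, or with the signal of the strongest promoter peak.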

Results

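H3K4me3, the trimethylated form of histone H3 lysine 4 found at the promoters of most active genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the midbrain of B6NCrl mouse embryos aged 12.5 days. The samples formed 1 group of 2 biological replicates. Replicate 1 was a pool of midbrains from 120 embryos and replicate 2 a pool from 88 embryos, with both sexes mixed. Replicate 1's own list held 30557 peaks over 38.1 Mb, and replicate 2's held 27663 peaks over 35.1 Mb. A pooled list, called on both replicates together, held 31812 peaks. The authors' replicated list held 23778 of these, covering 39.0 Mb. The lists carry no read counts, so the depth of the libraries is unknown, and a promoter without a listed peak is not thereby shown to lack the mark.

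The pools shared nearly all of their strong and promoter peaks and differed in short, weak peaks away from promoters. Of replicate 1's peaks, 77.9% (23805) were overlapped by a peak of replicate 2, and of replicate 2's peaks, 89.3% (24716) were overlapped by a peak of replicate 1. The same peaks placed at random within their chromosomes were overlapped in 2.57% and 2.82% of cases on average over 100 shuffles. Every peak in the highest quartile of either list by signal was shared, against 31.3% of replicate 1's lowest quartile and 60.7% of replicate 2's. The 6752 peaks found in replicate 1 alone had a median width of 224 bp, and the 2947 found in replicate 2 alone a median of 217 bp, against 1313 and 1181 bp for the shared peaks of each list. A protein-coding transcription start site (TSS) lay within 1 kb of 60.3% of replicate 1's shared peaks and 11.9% of its unshared peaks, and of 59.1% and 10.96% of replicate 2's. In base pairs, the lists had 33.0 Mb in common, 82.0% of the sequence covered by either.

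**Figure D1:**
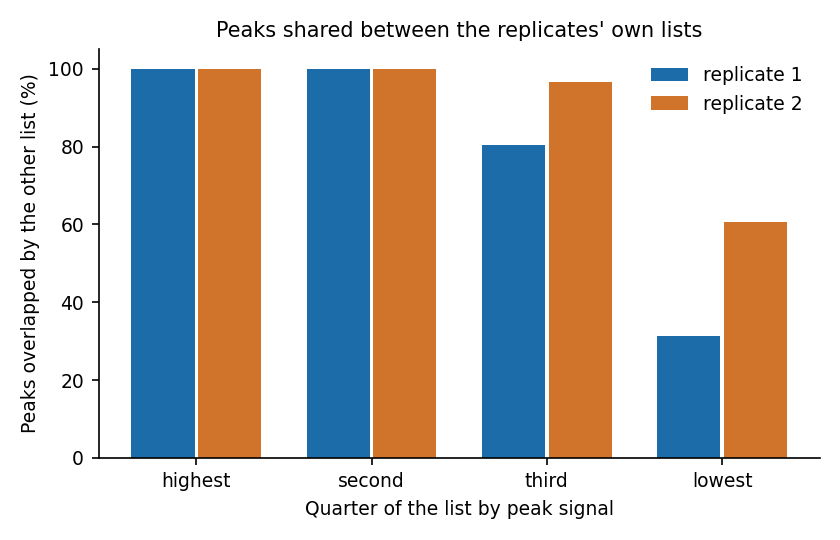
Share of each replicate's own peaks that a peak of the other replicate overlapped by at least 1 bp, in percent, for the 4 quartiles of each list ranked by the authors' signal value. Bars stand for the replicates; the highest quartiles were shared completely, and the lowest quartiles to 31.3% in replicate 1 and 60.7% in replicate 2.

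The strongest peak present in replicate 1 alone lay in an intron of Mid1, near the end of the X chromosome (169997390 to 169998035, mm10), with a signal of 12.7, rank 14196 in its list. The next lay within Rapgef6 on chromosome 11 (54597900 to 54598206, intronic), on an exon of F12 on chromosome 13 (55421136 to 55421607), and in intergenic sequence 18.4 kb from Efna1 on chromosome 3 and 142.1 kb from Mtx3 on chromosome 13. Their signal was at most 6.76. In replicate 2 alone, the strongest lay within Baz2b on chromosome 2 (60122305 to 60122680, intronic) and 1.93 kb from Mllt3 on chromosome 4 (88035295 to 88035649), each with a signal of 5.25, followed by peaks at Gm20425 and Gstt2 and 0.612 kb from a start site of Map3k12. Of the 23778 replicated peaks, 22165 (93.2%) overlapped a peak of both replicates' own lists, 1226 only of replicate 1's, 309 only of replicate 2's and 78 of neither. The peaks supported by both lists had a median width of 1518 bp, and the other classes medians of 362, 322 and 304.5 bp. With a −log10 q of at least 10 required of every peak, the shared part rose to 92.9% of replicate 1's peaks and 98.8% of replicate 2's.

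H3K4me3 peaks were concentrated at promoters, and the promoters of CpG-rich genes carried it almost without exception. Of the replicated peaks on assembled chromosomes, 59.5% lay within 1 kb of a protein-coding TSS, 15.8-fold more than the shuffled mean of 3.75% (permutation p = 0.0099, the smallest that 100 shuffles can give). The share was 49.7% in replicate 1's own list, 54.0% in replicate 2's and 47.3% in the pooled list. In the replicated list these peaks held 79.2% of the covered base pairs. A further 10.2% of peaks lay within 1 kb of another annotated TSS, 5.54% elsewhere on exons, 11.5% in introns and 13.4% between genes. A replicated promoter peak was listed for 14244 of 21938 protein-coding genes (64.9%). The replicates' own lists gave 14278.5 ± 71.4 genes (SD, n = 2), with 14168 genes in both, 161 in replicate 1 alone and 60 in replicate 2 alone. Joined into domains, the peaks of a marked promoter spanned a median of 2.22 kb in the replicated list. Across the 14168 genes, the domain widths of the replicates had Pearson's r = 0.931 on the log2 scale and Spearman's rho = 0.929, and 94.5% of genes were within 1.5-fold; genes are not independent replicates.

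Genes in the lowest decile of promoter CpG content had a promoter peak in 0.958% of cases, those in the fourth decile in 49.5% and those in the highest decile in 99.7%. The replicates' own lists gave 1.28% and 0.866% in the lowest decile, 50.7% and 49.0% in the fourth, and 99.7% in the highest decile in each. The median domain of marked genes widened from 1.2 kb in the third decile to 2.88 kb in the highest, while the few marked genes of the lowest decile had a median of 1.76 kb.

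**Figure D2:**
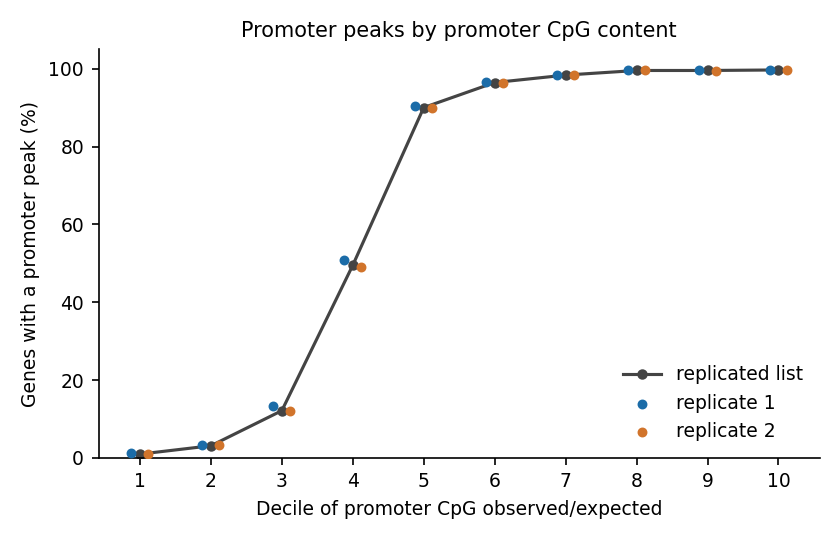
Percent of protein-coding genes with a promoter peak (vertical axis) in each decile of promoter CpG observed/expected ratio (horizontal axis, 1 is lowest). The line is the replicated list and the coloured points are the replicates' own lists; the share goes from 0.958% in decile 1 to 99.7% in decile 10.

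Genes of midbrain patterning, neural progenitors and most neuronal classes were marked without exception or nearly so, and genes of blood, liver, muscle, microglia and germ cells mostly were not. Against genes of like CpG content, none of the former lists was called in the main setting, and of the latter only that of germ cells. All 16 genes of midbrain and isthmus patterning had a promoter peak, among them Otx2, Pax3 and Meis2. So did all 12 genes of the floor plate and dopaminergic progenitors, all 13 of the midbrain GABAergic lineage, all 15 neural progenitor genes and all 15 pan-neuronal genes. Of the midbrain glutamatergic and motor lineage genes, 13 of 14 were marked; the exception was Phox2b, a homeobox gene of cranial motor neurons, and all 14 were marked with a 2.5 kb promoter window. Of 12 dopaminergic neuron genes, 9 were marked, and Th, Ddc and Aldh1a1, which encode enzymes of dopamine neurons, were not, although Ddc had a peak of 573 bp in replicate 1's own list. None of 12 liver genes had a promoter peak, including Alb, Afp and Apoa1. Among 15 erythroid and haematopoietic genes, 4 were marked, Runx1, Epor, Klf1 and Gypa, and none of the 7 globin genes was. Tmem119 was the only marked gene of 12 for microglia and macrophages, with a domain of 696 bp that measured 698 bp in replicate 1's own list and 191 bp in replicate 2's, and Cx3cr1, Csf1r, Aif1, Spi1 and Itgam had none. Dazl, with 0.892 kb, was the only marked gene of 12 for the germ line, where Ddx4, Sycp1, Sycp3, Tex101 and Prm1 had none. Of 14 heart and skeletal muscle genes, Myod1 (1.81 kb) and Nkx2-5 (446 bp; 208 bp in replicate 1's own list and 433 bp in replicate 2's) were marked, and Myh6, Myh7, Tnnt2, Actc1, Tbx5 and the other members were not. With the 2.5 kb window, 2 liver genes and 4 muscle genes were marked; at −log10 q of at least 10, 0 microglia genes and 1 muscle gene were.

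Compared with all other protein-coding genes by a two-sided Fisher's exact test, 16 of the 34 lists had a larger share of marked genes and 9 a smaller one after Benjamini-Hochberg adjustment. The lists with more were the 6 above, with adjusted p from 0.00315 for midbrain and isthmus patterning to 0.0361 for the glutamatergic and motor lineages, and 10 others. By the exact test, regulators of the telencephalon and diencephalon (15 of 15, adjusted p = 0.00404) and genes of the neural crest and peripheral neurons (11 of 11, adjusted p = 0.0173) were among them. Endoderm and mesoderm regulators (14 of 15, all but Pdx1, adjusted exact p = 0.0361), housekeeping genes (15 of 15), cell cycle genes (13 of 13) and immediate early genes (10 of 10) were others. The gene families with more were developmental transcription factors (159 of 179, 88.8%), ribosomal proteins (76 of 79, with Rpl10l, Rpl39l and Rpl3l unmarked), Zfp zinc finger genes (345 of 391) and replication-dependent histones (59 of 67). In the transcription factor families, Foxi1, Foxn1, Foxp3, Foxq1 and Foxr1 were among the 20 unmarked genes, although Foxq1 had a promoter domain of 3711 bp in replicate 1's own list and none in replicate 2's. Unmarked Zfp genes included Zfp345, Zfp352, Zfp366, Zfp385c and Zfp42, and unmarked histone genes Hist1h1d, Hist1h1t, Hist1h2aa, Hist1h2ao and Hist1h2ap.

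The lists with fewer by the exact test were liver (adjusted p = 1.67e-05), microglia and germ line (adjusted p = 0.000247 for each), muscle (adjusted p = 0.000407), erythroid genes (adjusted p = 0.00833) and 4 families. Olfactory receptors were marked in 3 of 1093 cases, Olfr94, Olfr658 and Olfr1033. Vomeronasal receptors were marked in 1 of 327, Vmn1r4, whose 2.15 kb domain also covered a promoter of Nt5c3. Keratins and keratin-associated proteins were marked in 7 of 106, with Krt10, Krt19 and Krt8 the widest (Krt8 had no promoter peak in replicate 2's own list), and clustered protocadherins in 22 of 57. The domains of Krt10 and Krt19 lay within the genes, more than 1 kb from the upstream end of each. The remaining 9 lists were not separated from other genes: dopaminergic neurons (9 of 12), hindbrain regulators (10 of 13, without Hoxa2, Hoxb1 and Gata1, which was also in the erythroid list), Hox clusters (23 of 39), oligodendrocytes and astrocytes (9 of 16), vascular endothelium (9 of 14), mesenchyme, meninges and pericytes (10 of 14), epidermis and epithelium (6 of 12), retina and pigment cells (6 of 12), and imprinted genes (10 of 11, all but Ndn). Of these, the Hox clusters were called with fewer at −log10 q of at least 10 (38.5%, adjusted exact p = 0.00328) and in the upper 5 CpG deciles (66.7%, adjusted p = 4.42e-10), epidermal genes with fewer in a 500 bp promoter window (33.3%, adjusted p = 0.0435), and imprinted genes with more in a 2.5 kb window (100%, adjusted p = 0.0278). The Hox share went the other way, above other genes and not called, in replicate 1's own list (28 of 39, 71.8%), the pooled list (31 of 39, 79.5%) and the 2.5 kb window (71.8%). Fisher's test describes these libraries, since genes are not replicates.

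Most of these differences in share were not called against genes of like CpG content. Against 10000 random lists matched on CpG decile, only the Zfp genes were marked more often (88.2% against 79.3%). Pan-neuronal genes were marked in 100% against 81.0% in matched lists (adjusted permutation p = 0.0755), and were called at the most upstream TSS (93.3% against 68.8%, adjusted permutation p = 0.0128) and without genes that share a domain (100% against 78.6%, adjusted permutation p = 0.0438). The other 6 neural and brain region lists with more were small, and their matched lists were marked in 89.8% to 97.6% of genes, which left little room for a higher share. The Hox clusters were marked in 59.0% of genes against 90.8% in matched lists, the germ line in 8.33% against 65.7%, protocadherins in 38.6% against 72.6%, histones in 88.1% against 96.9%, keratins in 6.6% against 24.9%, olfactory receptors in 0.274% against 6.18% and vomeronasal receptors in 0.306% against 2.70%, each with an adjusted random-list permutation p of 0.0034 or less. Among genes in the upper 5 CpG deciles only, 0 lists had more by Fisher's test and 4 had fewer, but 98.7% of other genes were marked there, so a list could hardly be called with more. The matched call of Zfp genes ended there (209 of 211 genes, 99.1% against 98.3%), and the keratin, olfactory and vomeronasal lists held 1 gene each, too few for a call. Histones, with more than other genes in the main setting, were called with fewer there (90.6% against 98.8%, adjusted exact p = 0.00128). Their matched call ended with a 2.5 kb promoter window. The exact test's call of endoderm and mesoderm regulators ended at −log10 q of at least 10 (adjusted p = 0.632) and in replicate 2's list alone (adjusted p = 0.141), that of the glutamatergic and motor lineages in replicate 1's list alone (adjusted p = 0.0582) and in the pooled list (adjusted p = 0.0603), that of protocadherins in the pooled list (adjusted p = 0.196), and that of histones without genes that share a domain (adjusted p = 0.634).

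Most neural lists had wider promoter domains than CpG-matched genes. The median domain was 9.04 kb for the midbrain GABAergic lineage, 4.31-fold that of CpG-matched marked genes, 7.17 kb (3.12-fold) for midbrain and isthmus patterning, 7.05 kb (3.36-fold) for the floor plate and dopaminergic progenitors and 6.81 kb (3.05-fold) for neural progenitors. It was 5.93 kb (2.61-fold) for the glutamatergic and motor lineages, 5.35 kb (2.45-fold) for regulators of the telencephalon and diencephalon, which lie anterior to the midbrain, and 4.03 kb (2.08-fold) for pan-neuronal genes. Hox genes, which pattern the body axis behind the midbrain, had narrow domains, with a median of 1.12 kb against 2.31 kb in matched genes. Each of these 8 lists differed from the matched lists with an adjusted random-list permutation p of 0.00045. In the replicates' own lists the GABAergic median was 8.52 and 8.81 kb, the midbrain patterning median 7.0 and 7.13 kb, and the Hox median 0.717 and 0.919 kb. The width and the order of the lists depended on joining. Without it the 7 wide lists kept their calls, with medians of 4963 bp (2.46-fold) for the GABAergic lineage, 5118 bp for midbrain patterning, 5004 bp for progenitors and 3353 bp (1.54-fold) for the glutamatergic and motor lineages. With peaks within 3 kb joined, the median was 9201 bp for the GABAergic lineage, less than the 10920 bp of midbrain patterning, 9794 bp of the glutamatergic and motor lineages, 9770 bp of the floor plate and 9520 bp of the telencephalon and diencephalon.

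**Figure D3:**
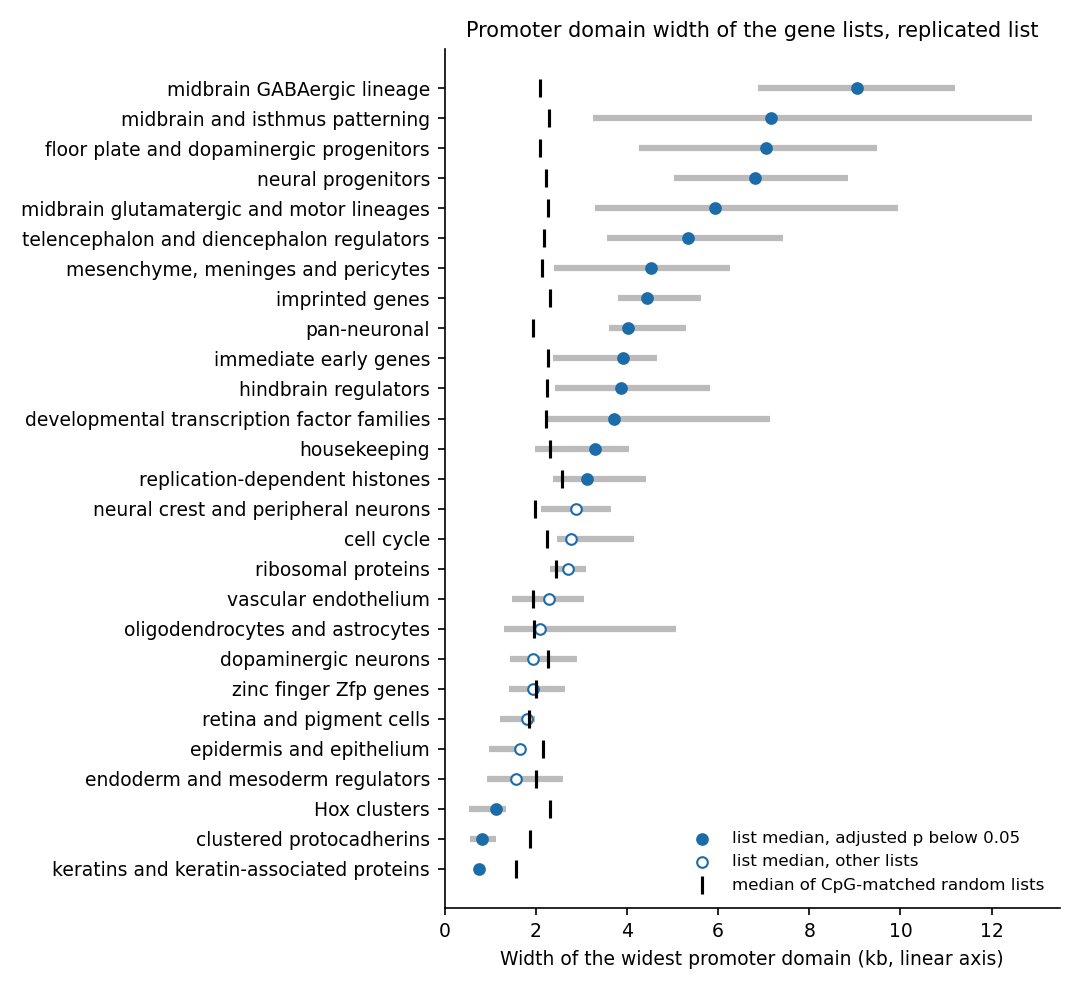
Width of the widest promoter domain of marked genes (horizontal axis, kb) in the 27 gene lists with at least 5 marked genes, replicated list. Points are list medians (filled where adjusted p was below 0.05), grey bars run between the quartiles, and ticks are the medians of CpG-matched random lists; with peaks within 1 kb joined, the GABAergic lineage is widest at 9.04 kb and keratins are narrowest at 0.745 kb.

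Values for single genes are given as the domain in the replicated list with mm10 coordinates, followed by the mean ± SD of the replicates' own lists (n = 2). In midbrain patterning, the domain of Meis2, a homeobox regulator of the tectum, spanned 22.8 kb on chromosome 2 (116053699 to 116076531; 22.6 ± 0.312 kb). That of Otx2, required for forebrain and midbrain, spanned 20.2 kb on chromosome 14 (48654990 to 48675187; 20.4 ± 0.6 kb), and that of Pax3, a dorsal neural tube regulator, 17.6 kb on chromosome 1 (78186766 to 78204372; 17.3 ± 0.279 kb). The floor plate list was led by Foxa1 with 12.9 kb (11.3 ± 1.67 kb), Lmx1b with 11.6 kb (11.3 ± 0.172 kb) and the morphogen gene Shh with 9.50 kb (9.48 ± 0.0354 kb). The GABAergic list was led by Gata3 with 20.3 kb on chromosome 2 (9869808 to 9890126; 19.6 ± 1.12 kb), in a domain that also covered 4930412O13Rik and 9230102O04Rik. Nkx2-2 followed with 15.0 kb (14915 bp in replicate 1's own list and 7126 bp in replicate 2's), and Slc32a1, the vesicular GABA transporter, with 11.6 kb (11.5 ± 0.158 kb). Slc17a6, the vesicular glutamate transporter of midbrain neurons, had 12.4 kb (12.5 ± 0.0870 kb), beside Barhl2 with 13 kb and Barhl1 with 10.7 kb. Among progenitor genes, Pax6 had 21.8 kb (19.7 ± 3.93 kb), Sox2 19.2 kb (18.7 ± 0.491 kb) and Msi1 14.3 kb (13.7 ± 1.21 kb). Myt1l had 13 kb, Tubb3 7.27 kb and Ina 7.21 kb among pan-neuronal genes, the last in a domain shared with Nt5c2. Lhx2 (21.9 kb; 21.5 ± 0.0926 kb), Six3 (15.8 kb; 15843 bp in replicate 1 and 7478 bp in replicate 2) and Emx2 (8.85 kb; 9.22 ± 1.35 kb) led the telencephalon and diencephalon list.

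Of the Hox genes, the widest were Hoxa1 (1.89 kb), Hoxc13 (1.82 kb) and Hoxa13 (1.53 kb), and Hoxa2, Hoxa3, Hoxa11, Hoxb1 and Hoxb2 were among the 16 without a replicated promoter peak; Hoxa2 (211 bp) and Hoxb1 (185 bp) had one in replicate 1's own list and Hoxa3 (223 bp) in replicate 2's. Protocadherins (median 0.824 kb against 1.87 kb, adjusted random-list permutation p = 0.00045) and keratins (0.745 kb against 1.57 kb, p = 0.0159) also had narrow domains. Pcdhgc3 with 3.82 kb, Pcdhgc4 with 3.49 kb and Pcdhga12 with 2.51 kb were the widest protocadherins, and Pcdha1, Pcdha11, Pcdha12, Pcdha2 and Pcdha3 were unmarked, although Pcdha12 had 910 bp in replicate 1's own list.

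Another 7 lists were also wider than matched genes, by factors from 1.22 to 2.12. Imprinted genes had a median of 4.44 kb (1.93-fold; Peg3 6.48 kb shared with Usp29, Mest 6.23 kb, Grb10 5.94 kb) and developmental transcription factors 3.71 kb (1.67-fold), each with adjusted random-list permutation p of 0.00045. Immediate early genes had 3.92 kb (1.73-fold, adjusted permutation p = 0.00308; Ier2 6.24 kb, Jun 5.26 kb, Junb 4.71 kb). The mesenchyme, meninges and pericyte list had 4.52 kb (2.12-fold, adjusted permutation p = 0.00045), led by the transcription factors Zic1, Prrx1 (6.79 kb; 6692 bp in replicate 1's own list and 4346 bp in replicate 2's) and Foxc1 (6.53 kb). Zic1 is also a regulator of the dorsal neural tube, and of the matrix and pericyte genes Col1a1, Col1a2 and Pdgfrb were marked and Col3a1, Rgs5, Lum and Dcn unmarked. Hindbrain regulators had 3.88 kb (1.73-fold, adjusted permutation p = 0.0036; Olig3 8.47 kb, Gbx2 8.01 kb, Mafb 6.21 kb), housekeeping genes 3.30 kb (1.44-fold, adjusted p = 0.0145; Ywhaz 6.07 kb, Polr2a 5.57 kb, Tbp 4.86 kb shared with Psmb1) and histones 3.13 kb (1.22-fold, adjusted p = 0.00308). The widest histone domain, 8.80 kb on chromosome 13 (23528844 to 23537647), covered Hist1h2af, Hist1h3g and Hist1h4h together. The 59 marked histone genes lay in 34 distinct domains, so shared domains counted more than once in their median. Without genes that share a domain, the histone median was 1977 bp, below matched genes and not called (adjusted permutation p = 0.0933). Widths of single peaks, with no joining, ended the calls of mesenchyme (2622 bp, adjusted permutation p = 0.149), hindbrain (2408 bp, adjusted p = 0.484) and housekeeping genes (adjusted p = 0.0778) and turned that of histones to 1.48 kb, below matched genes; the mesenchyme call also ended at −log10 q of at least 10 (adjusted p = 0.23), the hindbrain call in the pooled list (adjusted p = 0.0524) and the histone call with a 2.5 kb promoter window (adjusted p = 0.137). With peaks within 3 kb joined, the median rose to 6306 bp for histones and 5626 bp for developmental transcription factors.

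The other 10 lists tested for width were not separated from matched genes. Neural crest and peripheral neuron genes had a median of 2.87 kb (adjusted permutation p = 0.0618), with Tfap2a at 12.4 kb, Prdm12 at 8.80 kb and Six1 at 4.07 kb. Dopaminergic neuron genes had 1.94 kb against 2.27 kb, although Nr4a2, required for the dopaminergic fate, had 8.46 kb (8.33 ± 0.0127 kb) and Bnc2 4.09 kb. Cell cycle genes had 2.78 kb (Ccnd2 8.03 kb, Ccnd1 7.0 kb, Plk1 4.50 kb) and ribosomal protein genes 2.70 kb (Rpl35 6.85 kb, Rps18 6.71 kb and Rps2 5.91 kb, each in a domain shared with other genes). In the replicates' own lists, Rpl35 had 7049 bp in replicate 1 and 2820 bp in replicate 2. Oligodendrocyte and astrocyte genes had 2.09 kb (Olig2 7.56 kb, Pdgfra 6.55 kb), endothelial genes 2.29 kb (Esam 4.29 kb, Slc2a1 3.70 kb), Zfp genes 1.93 kb (Zfp503 14.5 kb, Zfp608 11.1 kb, Zfp516 9.03 kb) and retina and pigment genes 1.80 kb (Otx1 16.4 kb, Pmel 2.03 kb shared with Cdk2). Epidermal genes had 1.65 kb (Lor 2.25 kb, Krt10 1.81 kb) and endoderm and mesoderm regulators 1.57 kb (Gata6 3.55 kb, Foxf1 2.89 kb, Tbx3 2.71 kb). The Lor domain (92080095 to 92082348) covered the downstream end of the gene and stopped short of its upstream end at 92083142. The Krt10 domain (99385354 to 99387161) lay within the gene, more than 1 kb from its upstream end at 99389364. Some of these widths differed between the replicates' own lists, those of Olig2 (7786 bp in replicate 1 against 4324 bp in replicate 2), Pdgfra (8914 against 4363 bp) and Esam (4167 against 1116 bp). The endothelial median was 1.44 kb in replicate 2's own list, and 1.85 kb in replicate 1's, and the retina and pigment median 1.41 and 2.71 kb. Ribosomal genes were called wider in replicate 1's own list (adjusted permutation p = 0.0348), at the most upstream TSS (p = 0.0395) and without joining (p = 0.0493). Endoderm and mesoderm regulators were called narrower at the most upstream TSS (adjusted permutation p = 0.0395) and without joining (p = 0.0292), and neural crest genes wider without genes that share a domain (p = 0.0186). In the upper 5 CpG deciles, a setting chosen for widths after the data were seen, the 5 marked oligodendrocyte and astrocyte genes there were called wider (5066 bp against 2348 bp, adjusted permutation p = 0.00754). Medians without a change of call moved to 2657 bp for endoderm and mesoderm regulators with peaks within 3 kb joined, above matched genes (2076 bp), and to 3109 bp for retina and pigment genes in the pooled list.

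Among all protein-coding genes, Pou3f3, a POU-domain regulator of neural progenitors, had the widest promoter domain in the replicated list, 31.0 kb on chromosome 1 (42683842 to 42714844; 30.7 ± 0.174 kb). Nr2f2, an orphan nuclear receptor, followed with 29.0 kb on chromosome 7 (70342789 to 70371758; 27.5 ± 3.06 kb), and Pou3f2 with 22.9 kb on chromosome 4 (22476423 to 22499325; 22.7 ± 0.214 kb). Zic1 and Zic4 shared a domain of 22.8 kb on chromosome 9 (91349163 to 91371944), but in the replicates' own lists the domain at Zic1 spanned 14.5 ± 1.2 kb. The 20 widest further included Meis2, Lhx2, Pax6, Gata3 and its neighbours, Otx2, Sox2 and Pax3, given above, and Ebf3 (21.7 kb), Bahcc1 (18.9 kb), Lhx1 (18.1 kb), Nr2f1 (17.4 kb), Lhx5 (16.8 kb) and Mn1 (16.7 kb). The peaks with the highest signal were not the widest. They lay at the start sites of Lrrc47 (signal 79.0, 2.92 kb), Actg1 (75.9, 3.89 kb), Kdm5b (75.2, 3.08 kb), Arid1a (75.2, 8.88 kb) and 1110065P20Rik (74.3, 2.87 kb). The signal is the authors' own value per peak and is used here only within a list.

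Among domains more than 5 kb from every GENCODE start site, the widest in the replicated list lay upstream of En2, a homeobox gene of the midbrain and the isthmus. RefSeq places start sites of Gm35055 and Gm35223 within 1 kb of it. Of the replicated peaks on assembled chromosomes, 3962 (16.7%) were more than 5 kb from every annotated TSS, with 18.0% in replicate 1's own list and 16.5% in replicate 2's. Their median width was 626 bp, against 1655 bp for the other peaks. It was 395.5 bp in replicate 1's own list, 403 bp in replicate 2's and 410 bp in the pooled list, against 1177, 1243.5 and 1222.5 bp for the other peaks. The domain near En2 spanned 8.59 kb of intergenic sequence on chromosome 5 (28117768 to 28126357), 39.3 kb from the nearest start site of En2. In the replicates' own lists the widest piece of it measured 6.96 ± 2.20 kb (SD, n = 2); in replicate 1's it was 5407 bp, narrower than the 6915 bp of the domain near Trim27. The domain at the promoter of En2 itself spanned 12.4 kb (28163905 to 28176255). Other wide distal domains lay 5.81 kb from Trim27 on chromosome 13 (21166697 to 21173635; 6.94 kb; 6.89 ± 0.0361 kb), 11.9 kb from Cbx8 on chromosome 11 (119052851 to 119059183; 6.33 kb; 6.03 ± 0.0148 kb), within Ebf3 on chromosome 7 (137301531 to 137307647; 6.12 kb, exonic in part) and in an intron of Ostm1 on chromosome 10 (42631633 to 42637288; 5.66 kb; 2.38 ± 0.243 kb). The Ebf3 stretch was part of the 21.7 kb domain of that gene's promoter. The distal share was 13.1% at −log10 q of at least 10 and 19.7% in the pooled list, and no test between groups applies to it.

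**Figure D4:**
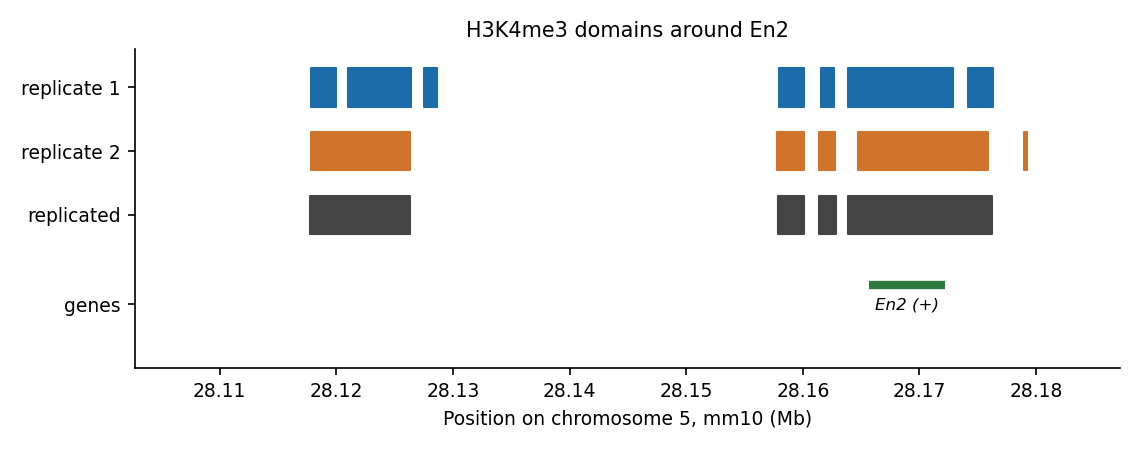
Domains (peaks within 1 kb joined) around En2 on chromosome 5, in Mb on mm10, in the own lists of replicates 1 and 2 and in the replicated list; the green bar is the GENCODE gene. The distal domain of 8.59 kb and the promoter domain of 12.4 kb are those of the replicated list. Replicate 2's list has 8.51 and 11.2 kb there. Replicate 1's list has the distal stretch in pieces of 2.165 and 5.41 kb and the promoter stretch in pieces of 8.99 and 2.15 kb. A further piece of 1.17 kb in replicate 1's list lies beyond the end of the distal domain.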

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

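The signals outside the comparisons were looked at after the main results were seen, and so were the tests named below as chosen afterwards. The replicated list held 13 peaks on unplaced or unlocalized scaffolds, which no gene comparison used. They were looked at because more were listed than the limit of 3 that a count of 0 allows. That limit is not a number expected there, so the count is not shown to be unusual. The replicate 1, replicate 2 and pooled lists held 17, 16 and 24. The 13 peaks lay on 6 scaffolds, with a median width of 823 bp. Promoters of lincRNA genes, which no gene list held, were marked in 474 of 5213 cases (9.09%) where every start site was more than 5 kb from a protein-coding TSS, against 505 and 463 genes in the replicates' own lists. The widest of these domains, 29.0 kb on chromosome 13 (83713584 to 83742579; 28.9 ± 0.116 kb, SD, n = 2), held the start sites of C130071C03Rik, the host of a mir-9 gene, and Gm26803. Gm44946 and Gm44948 lay within the 29.0 kb domain of Nr2f2, and Mir9-3hg had 15.8 kb on chromosome 7 (79496018 to 79511826; 14.9 ± 1.51 kb).

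The wide promoter domains of 7 neural lists (midbrain patterning, floor plate, GABAergic, glutamatergic and motor, progenitor, pan-neuronal, and telencephalon and diencephalon) were weighed against technical explanations; what the test without joining should show was written after its result was seen. If joining of neighbouring peaks made them wide, single peaks should be no wider than in matched genes, but the smallest ratio of list median to matched median over the 7 lists was 1.54 (the glutamatergic and motor lineages), although joining added to the width of each list. Hindbrain regulators, also called wider but not among the 7, had 2408 bp against 2160 bp without joining and lost their call (adjusted permutation p = 0.484), so joining is not excluded for them. With matching on CpG decile and number of annotated start sites, the smallest ratio was 2.03 (pan-neuronal), and with matching on CpG decile and signal of the strongest promoter peak 1.96 (pan-neuronal). These values argue against joining, start site number and peak strength as the whole cause in the 7 lists. What else made them wide stays open; the design holds no second tissue or stage, so no biological explanation was tested.

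The 3962 distal peaks were weighed against explanations from annotation, threshold and sequence; what the threshold test should show was written after its result was seen. Of these peaks, 12.3% (486) lay within 1 kb of a RefSeq transcript or tRNA start, against 1.29% of shuffled distal positions. With RefSeq starts added at the 5 kb limit itself, the distal share of replicated peaks fell from 16.7% to 13.1%. Start sites absent from GENCODE could thus account for a minority by either limit. The −log10 q was below 10 in 35.2% of them, and a CpG observed/expected ratio of at least 0.6 was found in 19.4%, against 49.7% of peaks near protein-coding start sites and 0.570% of shuffled positions. Neither RefSeq starts nor a −log10 q below 10 covers most distal peaks. The CpG ratio cannot decide this, since only 49.7% of peaks near protein-coding start sites reached 0.6. At these cuts 43.2% (1710) of the distal peaks had none of the properties. What these peaks are stays open, and no biological explanation was tested.

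The few and narrow Hox domains were weighed against CpG content, by the matched lists, and against hindbrain cells, by a comparison of paralog groups chosen after the values were seen; what each should show was written after its result was seen. Hox genes were marked in 59.0% of cases, against 90.8% of CpG-matched genes. Against all other genes, of which 64.9% were marked, the share was not called (Fisher's exact test, adjusted p = 0.569). Few and narrow were thus both judged against genes of like CpG content. The matched lists are therefore no separate test of CpG content as a cause. Hindbrain cells in the dissected tissue could add marks at paralog groups 1 to 4, which the hindbrain expresses: 6 of 12 genes (50%) were marked in groups 1 to 4 against 10 of 16 (62.5%) in groups 9 to 13 (Fisher's exact test, two-sided, p = 0.702). At −log10 q of at least 10 it was 5 genes of each, a larger share of groups 1 to 4, and the median widths were 1.30 kb in groups 1 to 4 and 0.868 kb in groups 9 to 13. With so few genes this source cannot be told apart from marks laid down in midbrain cells, and no biological explanation was tested.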

How the results depend on the processing

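The settings that left out genes sharing a domain, used other start site sets or took widths in the upper 5 CpG deciles were chosen after seeing the data; where a result moved, the cause was not tested unless the setting itself shows it. No paired analysis was possible because the samples form 1 group. The number of marked protein-coding genes stayed within 1.5 times of 14244 and the permutation call of peaks near start sites held under every setting run for each. With 21938 genes in all, that limit could hardly be passed upward. The number was 13872 at the most upstream TSS and 14466 with a 2.5 kb promoter window. The depth of the libraries is unknown, so its part in any of these shifts cannot be given.

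The overlap of the replicates rose with only peaks of −log10 q of at least 10, which leaves out weak peaks, to 92.9% of replicate 1's and 98.8% of replicate 2's peaks, and fell to 68.6% and 75.8% when at least 50% of both peaks had to overlap. The distal share, 16.7%, was 13.1% at −log10 q of at least 10, 13.1% with RefSeq start sites added, 19.7% in the pooled list, 11.4% beyond 10 kb and 22.8% beyond 2.5 kb, and 16.5% to 18.0% with 1 replicate left out. The share marked in the lowest CpG decile, 0.958%, was 1.37% in the pooled list, 0.456% and 2.01% with promoter windows of 500 bp and 2.5 kb, 1.73% with CpG content within 250 bp, and 0.866% to 1.28% with 1 replicate left out. In the highest decile, 99.6808% in the replicated list, it was 99.7264% in the pooled list, 99.9088% with the 2.5 kb window, 99.5896% at the most upstream TSS and 99.6352% with CpG content within 250 bp.

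With only genes of the upper 5 CpG deciles, which takes away the CpG-poor genes that most lists were compared with and leaves 98.7% of other genes marked, 0 lists had more marked genes and 4 fewer by Fisher's exact test, and 0 had more and 4 fewer than matched lists. The direction turned there for erythroid genes, vomeronasal receptors and keratins (100% marked, the last 2 also against matched lists), but each of these lists held 1 gene there, too few to decide anything. It also turned for ribosomal proteins (98.7%, 75 of 76 genes, near the other genes) and histones (90.6%, 58 of 64, called with fewer). The number of lists with more marked genes than matched lists was 2 in place of 1 at the most upstream TSS and 2 without genes that share a domain, with pan-neuronal genes gained in both. Without joining, 5 lists in place of 3 were narrower, and the histone median turned from wider to narrower (1476 bp). Without genes that share a domain the histone median was also below that of matched genes, but not called (1977 bp, adjusted permutation p = 0.0933). Of the other values for single lists under the alternatives, 847 kept their side of the threshold, 30 lost a call and 13 gained one. The 847 include uncalled values that changed direction, such as the Hox share by Fisher's test in the pooled list. Of the domain widths of named genes, 1268 stayed within 1 SD of the replicates and 271 moved by more.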

Other observations

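tRNA genes, which RefSeq annotates and the gene lists did not hold, coincided with some of the distal domains. A tRNA start lay within 1 kb of 81 distal peaks (2.04%), against a mean of 0.0207% and a maximum of 0.101% over 100 shuffles limited to distal positions (permutation p = 0.0099, the smallest they can give). The median width of these peaks was 1375 bp. The distal domain near Trim27 had 7 RefSeq tRNA starts within 1 kb, for methionine, leucine, glutamine and lysine tRNAs, and a start of Gm32298. The distal domain upstream of En2 had RefSeq starts of Gm35055 and Gm35223, while no RefSeq start lay within 1 kb of the domains near Cbx8, within Ebf3 or within Ostm1. These features were looked at after the positions of the domains were seen.

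On the sex chromosomes, with no matching on CpG content, 480 of 948 protein-coding genes of chromosome X were marked (50.6%), against 66.1% of 20807 autosomal genes and 4 of 183 genes of chromosome Y. The 4 were Kdm5d (1.17 kb), Uty (1.65 kb), Ddx3y (1.69 kb) and Eif2s3y (1.64 kb). Xist, the RNA that coats the inactive X chromosome, had a promoter domain of 3.62 kb, with 3.57 and 3.04 kb in the replicates' own lists. Both kinds of mark were thus present in these mixed-sex pools.

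By Hox cluster, 8 of 11 genes were marked in cluster a, 4 of 10 in b, 4 of 9 in c and 7 of 9 in d. The median Hox domain was 1.30 kb in paralog groups 1 to 4, 1.00 kb in groups 5 to 8 and 0.868 kb in groups 9 to 13. At −log10 q of at least 10, 5 genes of each of these sets were marked.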
